A study of Mus musculus with 12 samples.

How the data were processed

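RNA of adult mouse iris was measured on 12 arrays, 3 for each of 4 strains at 60 days of age. The strains, as the labels name them, were C57BL/6J, B6-Lystbg-J with a mutation in Lyst (called B6-Lyst here), B6-(Cg)TyrC-2J with a mutation in Tyr (B6-albino), and B6.D2(Tryp1-Gpnmb-)/SJ (B6-D2 congenic) with mutations in both Tyrp1 (spelled Tryp1 in the labels) and Gpnmb. Per the labels' protocols and the design text, irides were dissected in buffered saline, and the 4 eyes of 2 animals were pooled for each sample. Per the labels, the samples of a strain are biological replicates, so the spread between them holds animal, dissection and array variation together. Total RNA was extracted with a column kit, treated with DNase and made into biotinylated cRNA by the Affymetrix protocol, per the labels' protocols.

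The authors deposited 1 log2 value per probe set and array, and that scale was read from the values, which lay between about 3 and 14 on every array. Column medians lay between 6.05 and 6.13. The background correction, normalization, summary method and centring behind the deposited log2 values are not given in the sources used here, so the values were used as deposited. The number of arrays limits the precision of every value.

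Probe sets were named from the platform annotation supplied with the data, with symbols updated through a RefSeq gene table of assembly GRCm38.p6, which was used only for names and for which genes lie near each other. Of 45037 probe sets other than controls, 34945 had 1 gene symbol, 932 had several and 9160 had none, and 34741 matched the RefSeq table. A probe set with several symbols or none is unnamed here. The 64 Affymetrix control probe sets were left out of all tests. Probe sets with a mean over the 12 arrays at or above the 40th percentile (5.653 on the log2 scale) were tested, which left 27022. Where a gene had several tested probe sets, the one with the highest mean over all arrays represented it, which gave 13190 genes. The filter used the mean over all strains, so a probe set low in 1 strain could pass it. Where a strain mean lay below the filter value, which is not a measured background, a fold is given as a bound against that value, a choice made after the data were seen.

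Strains were compared with limma 3.58.1 in R 4.3.3. A single linear model with 1 mean per strain was fitted to all 12 arrays, and moderated tests with an intensity trend in the prior (prior degrees of freedom 3.57) were made for the 6 pairs of strains, two-sided. Benjamini-Hochberg adjustment ran over the tested probe sets of each pair, and a probe set was called at an adjusted p under 0.05. An F test asked for any difference among the strains. A check on simulated data of the B6-Lyst and C57BL/6J comparison, with 100 changed probe sets of each size among 27022, recovered 75% of log2 changes of 1 and 97% of log2 changes of 2, with the right sign in 100% and with 10 false calls. The B6-albino and B6-D2 congenic comparisons, left without change in the same simulation, gave 0 calls each.

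There were 27 gene lists, fixed in advance from textbook knowledge of the iris and of the tissues around it: melanin synthesis and melanosome, lysosome-related organelle biogenesis, lysosomal proteins, antioxidant and oxidative stress response, macrophage, lymphocyte, MHC class II presentation, complement and inflammatory mediators, interferon-stimulated genes, lens, photoreceptor and retina, retinal pigment epithelium, cornea, smooth muscle, skeletal muscle, stroma and extracellular matrix, vascular endothelium, Schwann cell and myelin, erythrocyte, immediate early genes, unfolded protein and heat shock response, circadian clock, sterol and fatty acid synthesis, cell cycle, glaucoma and anterior segment, oxidative phosphorylation, and sex-linked markers. Some genes stand on several lists, among them Ctss, Cd68 and Laptm5. Lists were tested with limma's camera with a preset correlation between genes of 0.01, adjusted over lists and pairs of strains, the 3 pairs with C57BL/6J and the 3 pairs of mutant strains as separate families. The test was repeated with the correlation estimated from the arrays. Lists with fewer than 3 tested members were left out of the test, a limit set after the data were seen. It removed the erythrocyte and sex-linked lists, with 1 tested member each.

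The genes named in the text follow a rule. In each comparison with C57BL/6J they are the mutated genes, the 8 largest rises and 8 largest falls among called genes whose 3 arrays per strain did not overlap, up to 4 members with the smallest p of each list called by camera, and up to 8 genes called in the same direction in all 3 mutant strains. In comparisons of mutant strains they are the 4 largest in each direction. Genes outside the rule were chosen after their values were seen. They are the list members named beyond the first 4, the genes of the strain against all others comparison, the genes near a mutated locus, and the unnamed probe sets and those of Per2, Rapgef3 and Brd8 in the B6-D2 congenic strain.

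Overlap between comparisons that share the C57BL/6J arrays was set against 100 simulations of unchanged groups and against the overlap of independent lists. Called genes within 20 Mb of a mutated gene were counted with a one-sided Fisher's exact test. Array measures (spike-in controls, differences of 3' and 5' control probe sets, tissue marker means) were compared between C57BL/6J and the other arrays with exact permutation tests, two-sided, over all 220 splits.

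The alternatives fixed before the data were examined were 75th percentile scaling, quantile normalization, no filter and a filter at the 60th percentile, a prior without trend, array weights, only the 6 arrays of the strains compared, a replicate block, representative probe sets only, an added 2-fold limit, an adjusted p under 0.01, the estimated correlation and a rank version for lists, other windows around the mutated genes, and each array left out in turn. The strains, tests, filter and gene lists were also set before the data were examined. Added after seeing the data were an RNA quality covariate (the mean 3' minus 5' difference of the Gapdh and actin controls), tissue covariates (lens, retina and cornea marker means), leaving out the 3 arrays with high Krt12, array weights estimated gene by gene, and the position test without the mutated genes.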

Results

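Gene expression in the iris was compared between C57BL/6J mice and mice of 3 strains with mutations that affect pigmentation. Each strain gave 3 arrays, each from the pooled irides of 2 animals aged 60 days. B6-Lyst mice (B6-Lystbg-J in the labels) carry a mutation in Lyst, the lysosomal trafficking regulator. B6-albino mice (B6-(Cg)TyrC-2J) carry a mutation in Tyr, which encodes tyrosinase, the first enzyme of melanin synthesis. B6-D2 congenic mice (B6.D2(Tryp1-Gpnmb-)/SJ) carry mutations in Tyrp1 and Gpnmb, which encode 2 melanosome proteins. Correlations between arrays of the same strain lay between 0.9465 and 0.9854 across probe sets, which are not independent replicates, and no pair of arrays was identical. Values are on the log2 scale, given as mean ± SD over 3 arrays, and a difference is given with its standard error (SE). The files give no detection call, and a strain mean below 5.653, the lowest mean over all arrays that was tested, is not shown to lie above background.

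Gpnmb transcripts were 9.33 ± 0.25 in B6-D2 congenic irides and 12.57 ± 0.62 in C57BL/6J irides (n = 3 each), a fall by 3.24 (SE 0.28, 9.43-fold, limma adjusted p = 0.000807). In the same strain Tyrp1 was 13.46 ± 0.11 against 13.44 ± 0.25 (adjusted p = 0.965). Lyst was 9.55 ± 0.25 in B6-Lyst irides against 9.52 ± 0.70 in C57BL/6J, a difference of 0.03 (SE 0.29, adjusted p = 0.966). Tyr was 12.15 ± 0.41 in B6-albino irides against 11.89 ± 0.58, a difference of 0.26 (SE 0.29, adjusted p = 0.644). Its other probe sets gave -0.54 (adjusted p = 0.244) and -0.19 (adjusted p = 0.58). A mutation need not alter the transcript level that a probe set measures, so the values of Lyst, Tyr and Tyrp1 check no label. The Gpnmb fall was called in all 6 fits that left out 1 array of either strain, and with the lens, retina and cornea marker means as covariates it was -3.12 with an adjusted p of 0.101. With only the 6 arrays of these strains its adjusted p was 0.0518. A second Gpnmb probe set differed by -1.48 (SE 0.24, adjusted p = 0.0613) in the B6-D2 congenic strain and by -1.09 (adjusted p = 0.0692) in the B6-albino strain.

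The arrays differed in technical measures and in tissue markers. The poly-A spike-in controls averaged 9.52 ± 0.27 on the C57BL/6J arrays, 6.44 ± 0.85 on B6-Lyst, 6.13 ± 0.11 on B6-albino and 6.34 ± 0.20 on B6-D2 congenic arrays. The difference of 3.22 between C57BL/6J and the other arrays had an exact permutation p of 0.00455, the smallest that 220 splits can give. Every C57BL/6J array lay at the high spike level and every mutant array at the low one. No label names a batch, and a labelling batch is inferred from this level alone. Such a batch and the C57BL/6J strain cannot be told apart, and no comparison with C57BL/6J could be made within a spike level. By record order, the C57BL/6J and B6-Lyst samples form a block apart from those of B6-albino and B6-D2 congenic. Comparisons of B6-Lyst with those other mutant strains therefore cross the blocks. The comparisons between mutant strains lay within the low level, where B6-Lyst replicate 3 was at 7.42 and the other mutant arrays between 5.89 and 6.54. The hybridization spike-in controls averaged 10.09 ± 0.04 on the B6-Lyst arrays, 10.43 ± 0.07 on B6-albino, 10.48 ± 0.05 on B6-D2 congenic and 10.65 ± 0.15 on C57BL/6J arrays (C57BL/6J against the rest, exact permutation p = 0.0227). The B6-Lyst arrays lay below all others in them, so that no comparison with B6-Lyst was matched in both kinds of spike. The 3' minus 5' difference of the actin controls was 4.30 on C57BL/6J replicate 3 and between 1.84 and 2.72 on the other arrays. Lens markers, which include the crystallins, averaged 8.57 ± 1.41 in C57BL/6J, 9.16 ± 1.98 in B6-Lyst, 11.28 ± 1.02 in B6-albino and 10.52 ± 0.41 in B6-D2 congenic irides (C57BL/6J against the rest, exact permutation p = 0.118). Retina markers averaged 7.30 ± 0.93, 8.08 ± 0.91, 8.51 ± 1.17 and 7.99 ± 1.10 in the same order (exact permutation p = 0.182). Krt12, a keratin of the corneal epithelium, was 12.86 on C57BL/6J replicate 1, 13.81 on B6-D2 congenic replicate 2 and 10.45 on B6-albino replicate 1, and between 5.96 and 7.12 on the other arrays.

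**Figure D1:**
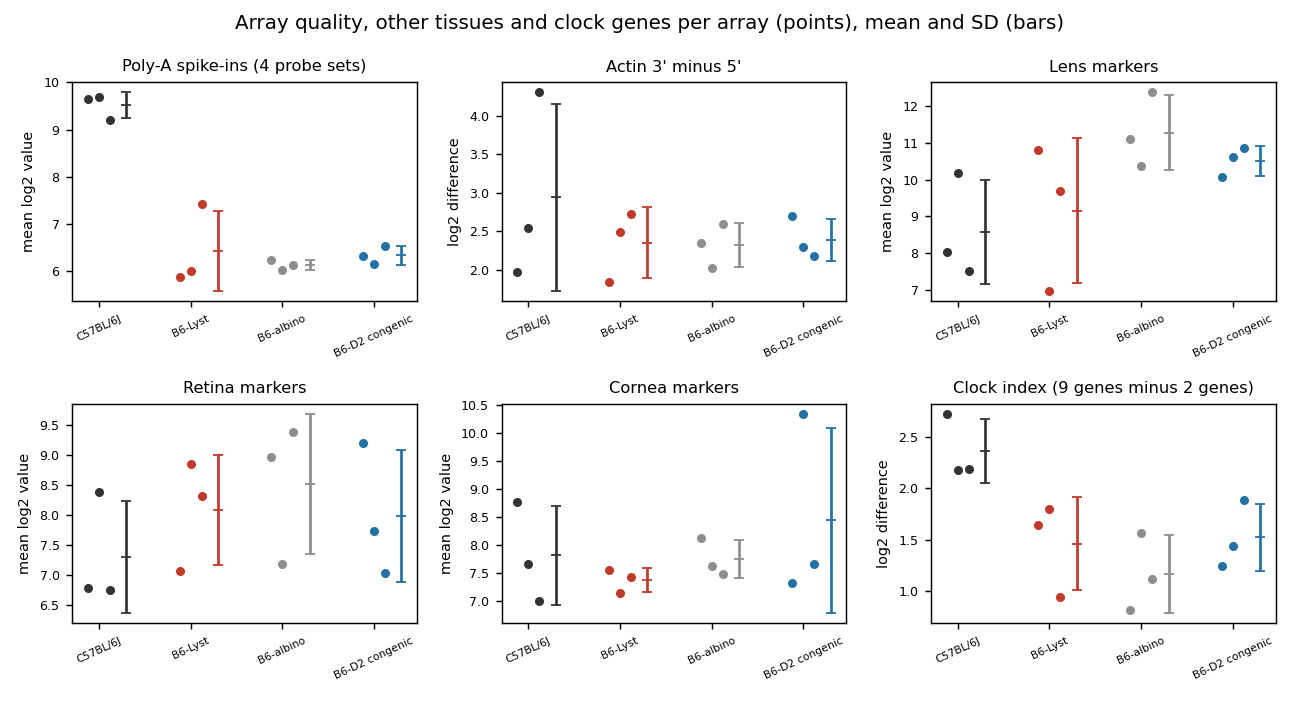
Array measures on the log2 scale for each of the 12 arrays by strain: poly-A spike-in controls, actin 3' minus 5' difference, lens, retina and cornea marker means, and a clock index (mean of 9 clock genes minus mean of 2 others). The spike-in controls averaged 9.52 on the C57BL/6J arrays and 6.30 on the mutant arrays.

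B6-Lyst irides had higher levels of transcripts of myeloid cells than C57BL/6J irides. Mmp12, the macrophage elastase, was 10.82 ± 0.46 against 4.99 ± 0.19 (n = 3 each), a rise of 5.83 (SE 0.19, limma adjusted p = 8.15e-09). Fabp4, a fatty acid binding protein of adipocytes and macrophages, rose by 5.01 (SE 0.25, adjusted p = 3.08e-07), and Il7r, a chain of the interleukin 7 receptor, by 4.97 (SE 0.17, adjusted p = 8.15e-09). Clec4d, a lectin receptor of myeloid cells, rose by 4.91 (SE 0.16), Itgb2 by 4.32 (SE 0.14) and Itgax by 4.05 (SE 0.19), the last 2 being chains of leukocyte integrins. Atp6v0d2, a proton pump subunit of osteoclasts and macrophages, rose from 5.34 ± 0.06 to 10.16 ± 0.18, by 4.82 (SE 0.11, adjusted p = 1.02e-09), and Glipr1 rose by 4.02 (SE 0.21). In C57BL/6J irides Mmp12, Fabp4 (4.38), Il7r (4.87) and Atp6v0d2 lay below 5.653, and against that value their rises were at least 35.9-fold, 13.3-fold, 18.2-fold and 22.7-fold, so that their order by size is not settled. The largest fall was that of Prpmp5, which encodes a proline-rich protein, from 10.16 ± 0.23 to 7.05 ± 0.49 (-3.12, SE 0.29, adjusted p = 8.82e-05). Ackr4, an atypical chemokine receptor, fell by 1.60 (SE 0.27, adjusted p = 0.00885) and Ciart, a repressor in the circadian clock, fell by 1.20 (SE 0.20, adjusted p = 0.00738).

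In all, 684 of 27022 probe sets were called between B6-Lyst and C57BL/6J, 339 higher and 345 lower, and 231 of them by at least 2-fold. At an unadjusted p under 0.05 there were 4712, and the 3 arrays of each strain did not overlap for 22.8% of probe sets, where chance gives 10%. Of the called probe sets, 197 of the 339 higher and 33 of the 345 lower ones were called in all 6 fits that each left out 1 array of these strains. The count was 252 without B6-Lyst replicate 1, 322 and 330 without C57BL/6J replicates 3 and 2, 349 and 433 without B6-Lyst replicates 3 and 2, and 448 without B6-albino replicate 1. Beside Hlf, Nr1d2, Stx17 and Cav2, taken up below, 5 named falls were called in at most 2 of those 6 fits. Among them were Cck, which encodes cholecystokinin (-1.54, SE 0.33, adjusted p = 0.0334, and 0.128 without B6-Lyst replicate 1) and the cation channel Trpc1 (-1.25, adjusted p = 0.0483, and 0.197 without that array). The other 3 were 4930426D05Rik (-1.23, adjusted p = 0.0348, and 0.164 without it), the sarcomere protein Myom2 (to 5.59, below 5.653, a fall of at least 1.17, adjusted p = 0.0446, and 0.196 without it) and the transporter Abca8a (-1.18, adjusted p = 0.0407, and 0.179 without it). Without B6-Lyst replicate 3 these 5 had adjusted p of 0.119, 0.153, 0.121, 0.126 and 0.13. Without C57BL/6J replicate 1 the calls of Cck (0.0577) and Myom2 (0.0727) ended. Without C57BL/6J replicate 2 those of Cck (0.0998), Trpc1 (0.145), 4930426D05Rik (0.102) and Abca8a (0.123) did. Without C57BL/6J replicate 3 those of Trpc1 (0.14), 4930426D05Rik (0.128), Myom2 (0.143) and Abca8a (0.118) did, and without B6-Lyst replicate 2 those of Cck (0.0534) and Myom2 (0.0507) did.

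**Figure D2:**
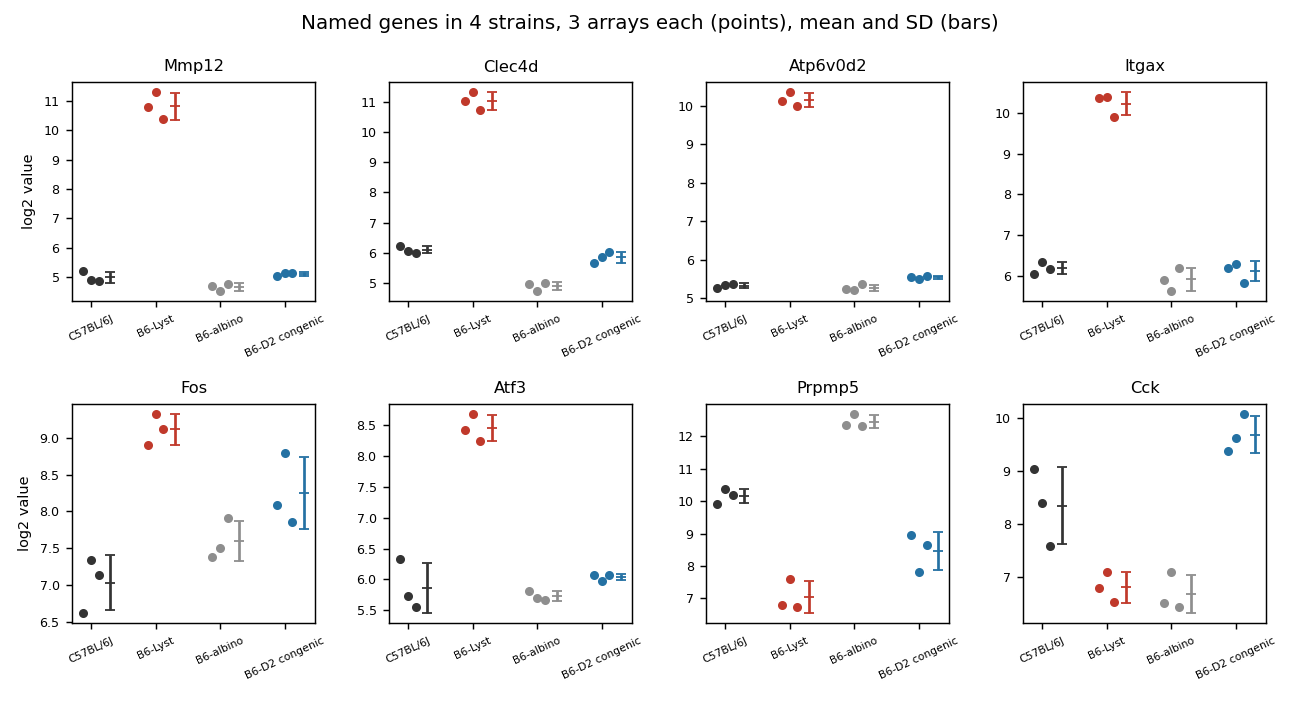
Expression of Mmp12, Clec4d, Atp6v0d2, Itgax, Fos, Atf3, Prpmp5 and Cck (log2 values) on each array by strain, with points for arrays and the mean and SD of the 3 arrays of a strain. Mmp12 averaged 10.82 in B6-Lyst irides and 4.99 in C57BL/6J irides.

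Of 21 tested macrophage markers, 16 rose in B6-Lyst irides against C57BL/6J (17 rose and 1 fell when adjusted over the list alone). The lysozyme gene Lyz2 rose by 3.86 (SE 0.25), Cd68 by 3.50 (SE 0.35), the signalling adaptor Tyrobp by 3.00 (SE 0.15) and the cathepsin gene Ctss by 2.61 (SE 0.15). The C1q chains rose by less, C1qb by 1.39, C1qc by 1.35 and C1qa by 0.87, and Csf1r, the receptor of macrophage growth factors, rose by 0.63. In the 6 fits that left out 1 array of these strains, Csf1r was never called (adjusted p between 0.0503 and 0.154). C1qc was called only without C57BL/6J replicate 1 (otherwise between 0.0585 and 0.147), and C1qa only without that array or B6-Lyst replicate 2 (otherwise between 0.0741 and 0.145). Markers that were not called were Mrc1 (0.63), Fcgr2b (0.20), Stab1 (-0.16), Pf4 (-0.51, and -0.07 without B6-Lyst replicate 2) and the scavenger receptor Cd163 (at 5.01 in B6-Lyst irides, below 5.653, and 0.46 lower against that value, adjusted p = 0.185). The list's median was 1.71 (camera adjusted p = 1.78e-26, adjusted p = 0.211 with an estimated correlation), and the list stayed called in every fit that left out 1 array. No called list in any comparison kept an adjusted p under 0.05 with an estimated correlation, and 4 lists of this comparison had an unadjusted p under 0.05 with it.

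**Figure D3:**
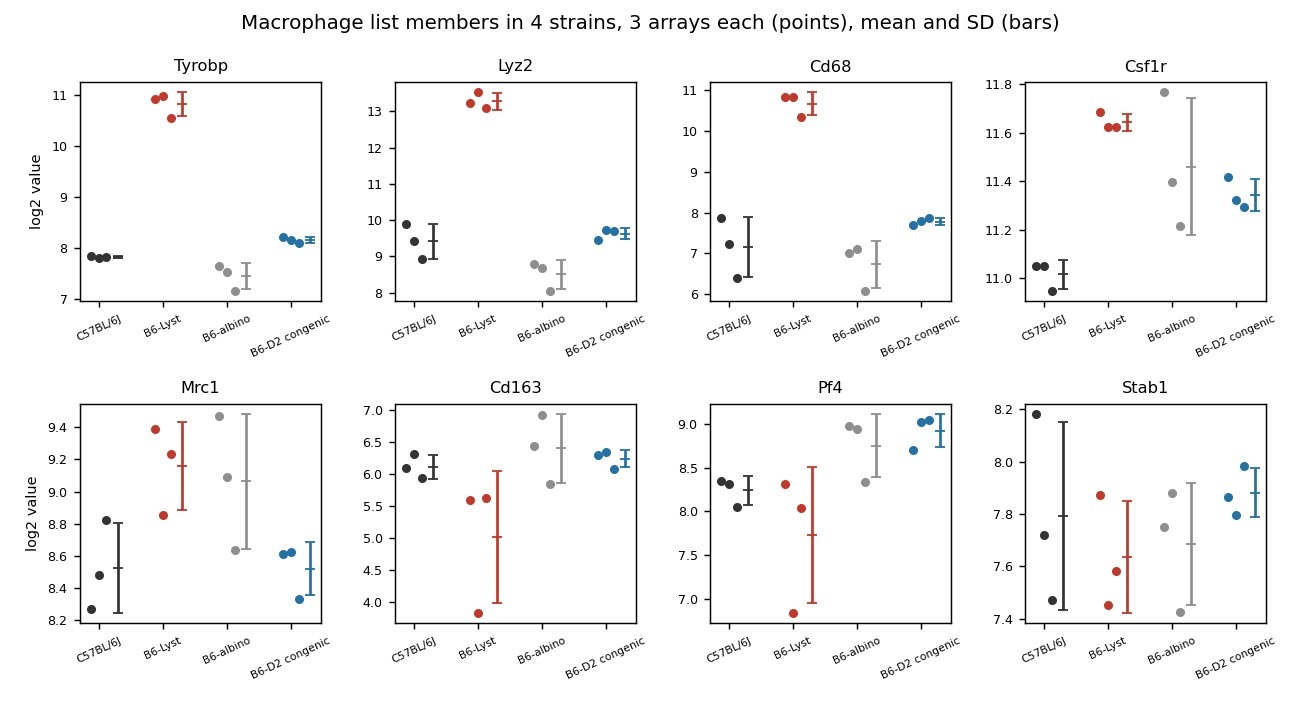
Expression of 8 macrophage markers (log2 values) on each array by strain, with points for arrays and the mean and SD of the 3 arrays of a strain. Tyrobp, Lyz2 and Cd68 were 3.00, 3.86 and 3.50 higher in B6-Lyst than in C57BL/6J irides, while Cd163 and Pf4 were not called.

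Lysosomal, immediate early and clock genes also moved in the B6-Lyst irides. Of 41 lysosomal genes, 9 rose (12 when adjusted over the list alone), 3 of them also on the macrophage list. The others were Atp6v0d2, the acid phosphatase Acp5 (2.35, SE 0.19), the glycosidases Gla (at least 1.92, from 5.37, below 5.653), Gusb (1.68) and Man2b1 (1.10), and the acid lipase Lipa (1.12). The calls of Gusb (adjusted p between 0.0631 and 0.113) and Man2b1 (between 0.0677 and 0.111) ended without C57BL/6J replicates 2 or 3 or B6-Lyst replicates 1 or 2. That of Lipa ended without C57BL/6J replicate 2 (0.0543) or B6-Lyst replicate 1 (0.0566). The median of the lysosomal list was 0.43 (adjusted p = 4.9e-12, adjusted p = 0.781 with an estimated correlation). Of 15 immediate early genes, Atf3 (2.58, SE 0.18), Fos (2.08, SE 0.26) and Egr1 (0.84, SE 0.14), which encode transcription factors, rose (4 when adjusted over the list alone). Their median was 0.46 (adjusted p = 9.34e-05, adjusted p = 0.415 with an estimated correlation). Of 15 clock genes, Ciart, Per2 (-1.05, SE 0.17), Per3 (-0.92, SE 0.15), Hlf (-0.66, adjusted p = 0.0311) and Nr1d2 (-0.57, adjusted p = 0.0332) fell, and 10 fell and 1 rose when adjusted over the list alone. Their median was -0.50 (adjusted p = 1.29e-05, adjusted p = 0.522 with an estimated correlation). The call of Hlf ended without C57BL/6J replicate 1 (0.058) or 2 (0.106) and without B6-Lyst replicate 1 (0.111), 2 (0.0852) or 3 (0.0926), and that of Nr1d2 without C57BL/6J replicate 1 (0.061) or 2 (0.0872) or B6-Lyst replicate 1 (0.125) or 3 (0.123). This comparison cannot tell a change from spike level (9.52 in C57BL/6J, 6.44 in B6-Lyst).

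Several smaller lists were called with few or no called members. Of 4 tested lymphocyte markers (15 on the array) Il7r and Cd4 (0.77, SE 0.13, adjusted p = 0.00842) rose, while Cd3e was -0.03 and Cd8a 0.05. Their median was 0.41 (adjusted p = 0.0013, 0.522 with an estimated correlation, 0.177 in the rank version), and their mean of 1.44 was 0.44 (0.00725) without a filter. Of 6 genes of MHC class II presentation only Ctss rose, with Cd74 at 0.37 and H2-Aa at 0.28. Their median was 0.29 (adjusted p = 0.0021, 0.781 with an estimated correlation). Of 28 antioxidant genes Srxn1, which encodes sulfiredoxin, rose (1.16, SE 0.20, adjusted p = 0.0101, and 0.0622 without B6-Lyst replicate 1). Of the 2 tested probe sets of Cat, 1 was called higher, which does not represent the gene. The antioxidant list (median 0.20, adjusted p = 0.0383, adjusted p = 0.834 with an estimated correlation) was not called without C57BL/6J replicate 3 (0.231), B6-Lyst replicate 1 (0.0557) or B6-Lyst replicate 2 (0.13), or with the RNA quality covariate (0.176). Its mean of 0.25 was 0.39 without C57BL/6J replicate 1 or without the 3 arrays with high Krt12. Of 15 cell cycle genes 0 were called and 15 were higher (3 called when adjusted over the list alone; Top2a at least 0.64, as it lay at 5.13 in C57BL/6J, below 5.653, with bounds between 0.415 and 1.061 when 1 array was left out; Cdkn1a 0.81). Their median was 0.40 (adjusted p = 0.000322, adjusted p = 0.781 with an estimated correlation). C3ar1, a complement receptor of myeloid cells, rose by 1.88 among 15 complement genes, whose list was not called (median 0.16, adjusted p = 0.0582).

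Lists of vascular endothelium, photoreceptors and interferon-stimulated genes were also called in B6-Lyst irides without a called representative probe set. All 15 vascular endothelium markers were lower (Flt1 -0.71, with 1 of its 3 tested probe sets called, and Cdh5 -0.55). Their median was -0.41 (adjusted p = 0.00195, adjusted p = 0.834 with an estimated correlation). Without C57BL/6J replicate 1, an array with high Krt12, the adjusted p was 0.16, and 0.11 without all 3 such arrays, while with the tissue covariates the list stayed called (mean -0.27, adjusted p = 0.0199). Of 20 photoreceptor markers 19 were higher (Gnat1 1.39, Opn1mw 0.95 against 5.653). Their median was 0.99 (adjusted p = 0.0178, adjusted p = 0.908 with an estimated correlation). The photoreceptor list was not called without C57BL/6J replicates 1 (0.389) or 3 (0.0509) or B6-Lyst replicates 2 (0.263) or 3 (0.12), without the 3 arrays with high Krt12 (0.411) or with the tissue covariates (0.741), and its mean of 0.84 was 1.38 without B6-Lyst replicate 1 and 1.41 without C57BL/6J replicate 2. Of 22 interferon-stimulated genes 20 were lower (Ifit3 -0.72, Ifit2 -0.65). Their median was -0.34 (adjusted p = 0.0204, adjusted p = 0.905 with an estimated correlation). Without C57BL/6J replicate 3, which had the largest actin 3' minus 5' difference, the mean of the interferon list turned from -0.31 to 0.06 (adjusted p = 0.173), and it was -0.56 without C57BL/6J replicate 2. It was -0.13 with the RNA quality covariate (adjusted p = 0.593) and with the tissue covariates (adjusted p = 0.248).

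B6-albino irides had higher Prpmp5 (12.46 ± 0.21 against 10.16 ± 0.23, n = 3 each, 2.29, SE 0.29, limma adjusted p = 0.0243) and lower Cd274, which encodes the checkpoint ligand PD-L1 (9.61 to 7.72, -1.88, SE 0.20, adjusted p = 0.0148), than C57BL/6J irides. Rises were also called for the carbonic anhydrases Car2 (1.61, SE 0.29, adjusted p = 0.0459) and Car6 (1.37, SE 0.15, adjusted p = 0.0148), the kinase Camk4 (1.48, SE 0.21), Wdfy1 (1.44, SE 0.16), the synaptotagmin Syt11 (1.40, SE 0.19), Tmem267 (1.32, SE 0.22) and Fgf13 (1.29, SE 0.19). Falls were called for Myom2 (-2.09, SE 0.28, adjusted p = 0.0246), Mpzl2 (-1.71, SE 0.31), Elobl (-1.57, SE 0.28), Art3 (-1.47, SE 0.19), Ciart (-1.29, SE 0.20, adjusted p = 0.0327), Eml2 (-1.21, SE 0.21) and Clec4d (-1.20, SE 0.16). Myom2 (4.73) and Clec4d (4.91) lay below 5.653 in B6-albino irides, so that their sizes are not settled. Lyz1, a lysozyme gene, fell by 1.03 (SE 0.16, adjusted p = 0.0357).

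There were 94 calls between B6-albino and C57BL/6J, 44 higher and 50 lower, with 5246 at an unadjusted p under 0.05 and arrays that did not overlap for 23.5% of probe sets, where chance gives 10%. The share of higher calls was 46.8%, and 31.1% with 75th percentile scaling or 29.7% with quantile normalization. None of the 94 calls was made in all 6 fits that left out 1 array of these strains. The counts were 0 without B6-albino replicate 1 or 3, 7, 19 and 37 without C57BL/6J replicates 3, 2 and 1, 9, 29 and 200 without B6-Lyst replicates 1, 3 and 2, and 131, 37 and 54 without B6-D2 congenic replicates 1, 2 and 3. With the lens, retina and cornea marker means as covariates, or without the 3 arrays with high Krt12, the count was 0. The differences of Prpmp5, Wdfy1 and Car6 were then 2.49, 1.59 and 1.47 with the covariates and 2.23, 1.34 and 1.43 without those arrays, while that of Car2 was 0.80 with the covariates. Every named call above thus ended without B6-albino replicate 1, where the adjusted p of Prpmp5, Cd274 and Myom2 were 0.117, 0.108 and 0.117, and without B6-albino replicate 3, where they were 0.0901, 0.0731 and 0.0966.

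Lens markers had the largest median among the lists in the B6-albino comparison. Of 20 lens markers 0 were called and 19 were higher (16 called when adjusted over the list alone), with the crystallins Cryba4 at 3.77 (SE 1.17, adjusted p = 0.128), Cryba2 at 3.58 (SE 1.09) and Crygn at 2.77 (SE 0.63). Their median was 2.78 (adjusted p = 8.07e-07, adjusted p = 0.781 with an estimated correlation). All 20 photoreceptor markers were higher (Gnat1 1.86, Sag 1.69). Their median was 1.28 (adjusted p = 0.00169, adjusted p = 0.834 with an estimated correlation), without a call when C57BL/6J replicate 1 (0.149) or B6-albino replicate 3 (0.187) was left out, and the list's mean of 1.26 was 1.95 without B6-albino replicate 2. Of 9 pigment epithelium markers 0 were called (6 when adjusted over the list alone; Rgr 2.51, Rpe65 2.26). Their median was 0.77 (adjusted p = 0.017, adjusted p = 0.781 with an estimated correlation), again without a call when C57BL/6J replicate 1 (0.0917) or B6-albino replicate 3 (0.0627) was left out. Lens markers averaged 11.28 ± 1.02 on these arrays against 8.57 ± 1.41. With the tissue covariates the adjusted p of the lens, photoreceptor and pigment epithelium lists were 0.388, 0.529 and 0.248, and without the 3 arrays with high Krt12 those of the photoreceptor and pigment epithelium lists were 0.33 and 0.189.

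Beside these tissue markers, 22 of 22 interferon-stimulated genes were lower in B6-albino irides (0 called, 4 when adjusted over the list alone; Rsad2 -1.27, SE 0.35, adjusted p = 0.107; Gbp2 -0.97, SE 0.27). Their median was -0.51 (adjusted p = 3.19e-07, adjusted p = 0.781 with an estimated correlation). The list's mean of -0.61 was -0.25 without C57BL/6J replicate 3, -0.38 with the RNA quality covariate and -0.05 (adjusted p = 0.231) with the tissue covariates. Of 40 genes of oxidative phosphorylation 39 were higher with 0 called (Ndufa1 0.61, Atp5pb 0.55). Their median was 0.38 (adjusted p = 1.19e-05, adjusted p = 0.834 with an estimated correlation). The list's mean of 0.37 was 0.19 without C57BL/6J replicate 3, 0.16 with the RNA quality covariate and 0.13 with quantile normalization, and the list stayed called in each. Of 15 clock genes Ciart fell (2 rose and 4 fell when adjusted over the list alone; Arntl 1.08, adjusted p = 0.0608; Per2 -0.70, adjusted p = 0.0827, with its other tested probe set called lower). Their median was -0.25 (adjusted p = 0.00391, adjusted p = 0.781 with an estimated correlation). The clock list was not called with the tissue covariates (0.0555) or without the 3 arrays with high Krt12 (0.0676), and its mean of -0.24 was -0.16 (0.033) without C57BL/6J replicate 1. Cell cycle genes (0 of 15 called, 2 when adjusted over the list alone; Top2a at least 0.78 against 5.653; median 0.40, adjusted p = 0.0227, adjusted p = 0.834 with an estimated correlation) lost their call without C57BL/6J replicate 1 (0.168) or B6-albino replicate 1 (0.054), with the tissue covariates (0.0893), with a filter at the 60th percentile (0.538) or without the 3 arrays with high Krt12 (0.252). Complement genes (0 of 15 called; Ccl5 -0.32; median -0.22, adjusted p = 0.0117, adjusted p = 0.781 with an estimated correlation) lost it without C57BL/6J replicate 1 (0.104), with the tissue covariates (0.0608), with a filter at the 60th percentile (0.183) or without the 3 arrays with high Krt12 (0.1). Their mean of -0.18 was -0.27 without C57BL/6J replicate 3 and -0.29 with the RNA quality covariate. Vascular endothelium markers (0 of 15 called; Cdh5 -0.52; median -0.36, adjusted p = 0.012, adjusted p = 0.834 with an estimated correlation) lost it without C57BL/6J replicate 1 (0.347) or B6-albino replicate 1 (0.139), and with the tissue covariates (0.429), and their mean of -0.25 was 0.11 without the 3 arrays with high Krt12, -0.42 without B6-albino replicate 2 and with the RNA quality covariate, and -0.38 without C57BL/6J replicate 3.

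B6-D2 congenic irides differed from C57BL/6J in 11 probe sets, 2 higher and 9 lower, including the Gpnmb fall by 3.24. Tmem267, which encodes a membrane protein, was the other called gene, at 8.20 ± 0.19 against 6.55 ± 0.22 (n = 3 each, 1.65, SE 0.22, limma adjusted p = 0.035). Its call ended without C57BL/6J replicates 1 (0.0526), 2 (0.0776) or 3 (0.145) or B6-D2 congenic replicates 2 (0.161) or 3 (0.11). A probe set unnamed here fell from 9.20 ± 0.36 to 3.37 ± 0.17 (adjusted p = 3.77e-07), at least 11.7-fold against 5.653. Another fell from 6.72 to 3.63 (at least 2.09-fold), 3 more were lower (-1.95, -1.11 and -0.98, the last to 5.16) and 1 was higher (0.72). Single probe sets of Per2 (-1.19), Rapgef3 (-1.53) and Brd8 (-0.84), which do not represent their genes and were singled out after their values were seen, fell with an adjusted p of 0.035 each. At an unadjusted p under 0.05 there were 4818 probe sets, and arrays did not overlap for 18.1%, where chance gives 10%. Of the 9 lower calls, 4 were made in all 6 fits that left out 1 array, and neither of the 2 higher ones was. The count was 39, 5 and 5 without C57BL/6J replicates 1, 2 and 3, 5, 7 and 5 without B6-Lyst replicates 1, 2 and 3, 6 and 5 without B6-albino replicates 1 and 3, and 44, 5 and 4 without B6-D2 congenic replicates 1, 2 and 3. The share of higher calls was 18.2%, and 28.2% with 75th percentile scaling or 38.9% with quantile normalization.

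Cell cycle, chaperone and clock lists were called in B6-D2 congenic irides without a called representative probe set. All 15 cell cycle genes were higher (9 called when adjusted over the list alone), with Rrm2, a subunit of ribonucleotide reductase, at least 1.11 higher (adjusted p = 0.119), Top2a at least 0.89 and Ccnd1 1.35 (SE 0.32). Rrm2 (4.68) and Top2a (5.13) lay below 5.653 in C57BL/6J irides. Without B6-D2 congenic replicate 2, an array with high Krt12, their bounds were 0.54 and 0.58. Their median was 0.59 (adjusted p = 5.78e-06, adjusted p = 0.781 with an estimated correlation). Of 23 genes of the unfolded protein and heat shock response 19 were higher (4 called when adjusted over the list alone; the chaperones Calr 0.65, SE 0.12, adjusted p = 0.0695, and Hspa5 0.52). Their median was 0.29 (adjusted p = 0.00381, adjusted p = 0.781 with an estimated correlation), and their mean of 0.34 was 0.22 (0.0101) without C57BL/6J replicate 3. Of 15 clock genes 11 were lower (1 rose and 5 fell when adjusted over the list alone; Ciart -1.11, adjusted p = 0.0663; Per3 -0.90, adjusted p = 0.0613). Their median was -0.29 (adjusted p = 3.36e-05, adjusted p = 0.522 with an estimated correlation), and their mean of -0.31 was -0.20 (0.00458) without the 3 arrays with high Krt12. Of 40 oxidative phosphorylation genes 38 were higher (Uqcrq 0.74, Ndufa1 0.51). Their median was 0.34 (adjusted p = 2.95e-05, adjusted p = 0.834 with an estimated correlation). The list's mean of 0.35 was 0.17 without C57BL/6J replicate 3, 0.19 without B6-D2 congenic replicate 3, 0.18 with the RNA quality covariate and 0.18 with quantile normalization, and the list stayed called in each.

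The tissue markers of the B6-D2 congenic irides lay on the same side as those of B6-albino. All 20 lens markers were higher with 0 called, over all probe sets or when adjusted over the list alone (Cryba2 2.94, Crybb3 2.65). Their median was 2.20 (adjusted p = 0.000223, adjusted p = 0.834 with an estimated correlation). Of 9 pigment epithelium markers 8 were higher (2 called when adjusted over the list alone; Rgr 2.00; median 0.65, adjusted p = 0.0124, adjusted p = 0.781 with an estimated correlation), without a call when C57BL/6J replicate 1 was left out (0.106) or with the tissue covariates (0.104). Without the 3 arrays with high Krt12 the lens list was not called (0.105), nor were the unfolded protein (0.0552) and vascular endothelium (0.617) lists. Antioxidant genes (0 of 28 called; Gstm1 1.27; median 0.34, adjusted p = 0.0446, adjusted p = 0.834 with an estimated correlation) had no call without C57BL/6J replicate 3 (0.202) or B6-D2 congenic replicates 2 (0.0981) or 3 (0.125), with the RNA quality covariate (0.134), the tissue covariates (0.074), quantile normalization (0.102) or a filter at the 60th percentile (0.109), or without the 3 arrays with high Krt12 (0.0552). Vascular endothelium markers (0 of 15 called, 1 lower when adjusted over the list alone; Sox17 -0.80; median -0.35, adjusted p = 0.000756, adjusted p = 0.799 with an estimated correlation) had none without C57BL/6J replicate 1 (0.167), and their mean of -0.29 was -0.17 without B6-D2 congenic replicate 2 and -0.10 (0.0494) with the tissue covariates. Interferon-stimulated genes (0 of 22 called; Rsad2 -0.85; median -0.25, adjusted p = 0.00265, adjusted p = 0.834 with an estimated correlation) turned to a mean of 0.09 (adjusted p = 0.373) without C57BL/6J replicate 3 and of 0.17 (adjusted p = 0.483) with the tissue covariates, and had no call with the RNA quality covariate (0.211), while their mean of -0.27 was -0.53 without C57BL/6J replicate 2.

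**Figure D4:**
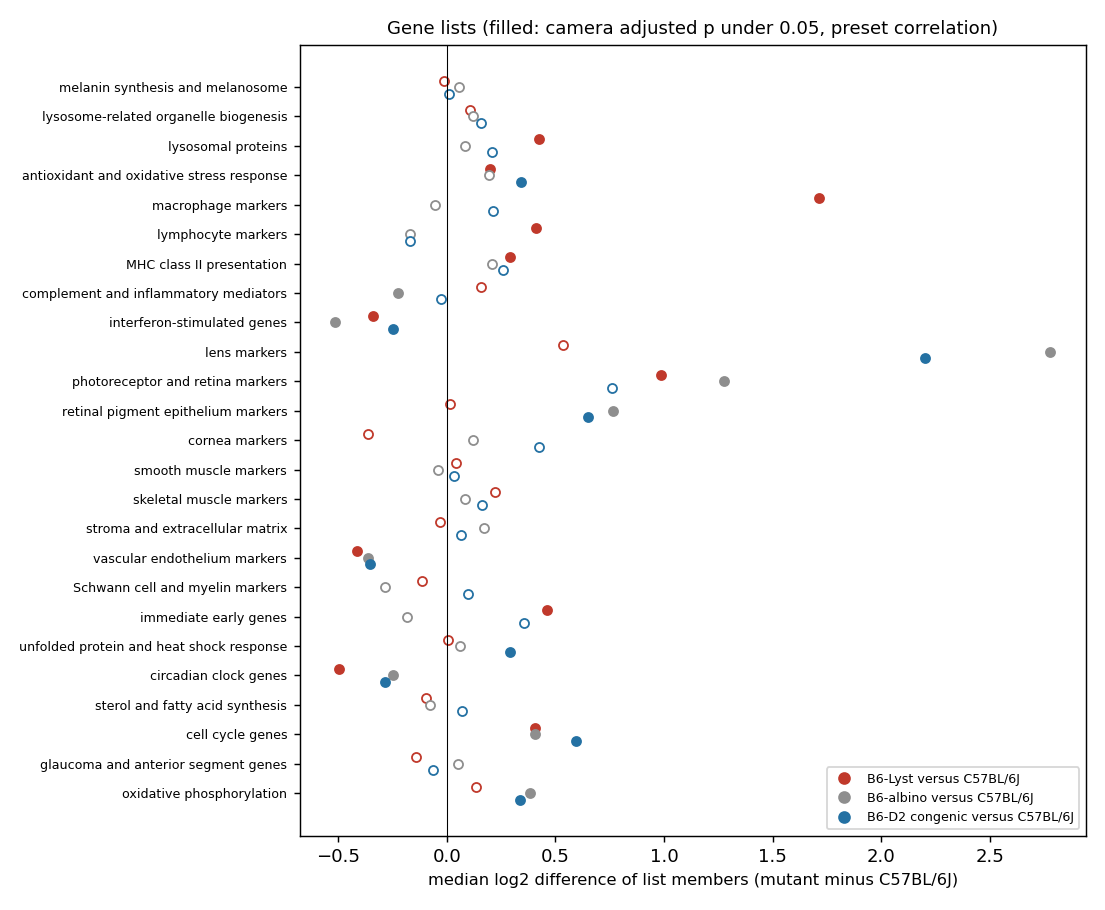
Median log2 difference from C57BL/6J of each gene list in the 3 mutant strains, with filled points for lists called by camera at the preset correlation (adjusted p under 0.05). The macrophage list had a median of 1.71 in B6-Lyst, -0.06 in B6-albino and 0.21 in B6-D2 congenic irides.

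Pigment and organelle lists were not called in any mutant strain against C57BL/6J. The medians of 24 melanin and melanosome genes in B6-Lyst, B6-albino and B6-D2 congenic irides were -0.02, 0.06 and 0.01 (adjusted p = 0.816, 0.953 and 0.05), with Gpnmb as the 1 called member, in the B6-D2 congenic strain. Their camera direction was down in the B6-albino and B6-D2 congenic irides against medians above 0, and in the latter the mean was -0.15. The 24 genes of lysosome-related organelle biogenesis had medians of 0.11, 0.12 and 0.16 (adjusted p = 0.125, 0.561 and 0.356), and among them Stx17, a syntaxin, fell by 0.47 (adjusted p = 0.0474) in B6-Lyst irides but was not called in any of the 6 fits that left out 1 array (between 0.0612 and 0.221). Glaucoma and anterior segment genes had medians of -0.14, 0.05 and -0.06 (adjusted p = 0.288, 0.992 and 0.503), and Cav2, which encodes a caveolin, fell by 0.66 (adjusted p = 0.0263) in B6-Lyst irides, with a left-out call only without C57BL/6J replicate 2 (otherwise between 0.051 and 0.116). In B6-albino irides their camera direction was down against a median above 0, and in B6-D2 congenic irides their mean was 0.07.

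Lists of the other tissues of the anterior eye were not called against C57BL/6J either. In the order B6-Lyst, B6-albino and B6-D2 congenic, cornea markers had medians of -0.36, 0.12 and 0.43 (adjusted p = 0.818, 0.991 and 0.244), with a mean of -0.04 in B6-albino irides. Smooth muscle markers had 0.04, -0.04 and 0.03 (adjusted p = 0.992, 0.244 and 0.507), with camera directed down in all 3. Skeletal muscle markers had 0.22, 0.08 and 0.16 (adjusted p = 0.24, 0.215 and 0.953), stroma genes -0.03, 0.17 and 0.07 (adjusted p = 0.321, 0.215 and 0.859), and Schwann cell markers -0.12, -0.29 and 0.10 (adjusted p = 0.431, 0.0515 and 0.989). Genes of sterol and fatty acid synthesis had -0.10, -0.08 and 0.07 (adjusted p = 0.337, 0.377 and 0.779), with camera directed down in all 3. None of the members of these 6 lists was called in a comparison with C57BL/6J. Hba-a1, the 1 tested erythrocyte marker, differed by 0.22, -0.20 and -0.07, and Xist, the 1 tested sex-linked marker, by -0.17, 0.30 and -0.15. Other members of both lists are on the array but did not pass the filter. Among them Eif2s3y had strain means between 3.62 and 3.67, where those of Xist lay between 12.14 and 12.61.

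Set against the B6-albino and B6-D2 congenic irides, within the low spike level, B6-Lyst irides had the same leading rises. Mmp12 was 6.16 higher than in B6-albino (SE 0.19, limma adjusted p = 5.19e-09) and 5.71 higher than in B6-D2 congenic irides, Clec4d 6.11 and 5.16, Fabp4 5.10 and 4.74, and Il7r 4.97 and 4.79. Mmp12, Fabp4 and Il7r lay below 5.653 in both other strains and Clec4d (4.91) in B6-albino, so that these are sizes against a level not shown above background. Prpmp5 was 5.41 lower than in B6-albino (-5.41, SE 0.29, adjusted p = 5.33e-07), and Wdfy1 (-1.68), the cytochrome P450 gene Cyp4b1 (-1.45) and Id4 (-1.40) were lower too. Against B6-D2 congenic irides Cck was lower (-2.88, SE 0.33, adjusted p = 0.000485), as were Prpmp5 (-1.42, adjusted p = 0.0487), Zfp467 (-0.85, adjusted p = 0.0238) and Pdcd4 (-0.83, adjusted p = 0.024). The calls of the last 3 ended without B6-Lyst replicate 1 (0.252, 0.133 and 0.0906), B6-Lyst replicate 3 (0.223, 0.104 and 0.0899) or B6-D2 congenic replicate 1 (0.148, 0.0647 and 0.0577). Those of Zfp467 (0.0542) and Pdcd4 (0.117) also ended without B6-D2 congenic replicate 2, and those of Prpmp5 (0.22) and Zfp467 (0.127) without B6-D2 congenic replicate 3. There were 498 calls against B6-albino, 343 of them higher, and 252 against B6-D2 congenic irides, 241 of them higher. At an unadjusted p under 0.05 there were 5160 and 2622, and arrays did not overlap for 30.2% and 17.2% of probe sets, where chance gives 10%. The first count was 232, 246 and 321 without B6-Lyst replicates 1, 2 and 3 and 241 and 278 without B6-albino replicates 1 and 3. The share of higher calls against B6-albino was 68.9%, and 79.2% with 75th percentile scaling or 84.5% with quantile normalization.

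Of the 21 macrophage markers, 14 were higher in B6-Lyst than in B6-albino irides (16 higher and 2 lower when adjusted over the list alone; median 1.73, adjusted p = 2.29e-26, adjusted p = 0.0736 with an estimated correlation). There were 13 higher than in B6-D2 congenic irides (17 and 2 over the list alone). Their median was 1.55 (adjusted p = 4.34e-35, 0.0736 with an estimated correlation). Of 41 lysosomal genes 7 were higher in each comparison (11 and 9 over the list alone; medians 0.28 and 0.10). Adjusted p were 4.71e-10 and 3.18e-13, and 0.705 and 0.689 with an estimated correlation. Il7r and Cd4 of 4 lymphocyte markers were higher in both (adjusted p = 9.08e-06 and 1.08e-07, 0.0946 and 0.0736 with an estimated correlation). C3ar1 of 15 complement genes was higher in both (adjusted p = 9.08e-06 and 0.000209, 0.137 and 0.213 with an estimated correlation). So was Ctss of 6 genes of MHC class II presentation (medians 0.06 and 0.08). Adjusted p were 0.0328 and 0.0142, and 0.841 and 0.774 with an estimated correlation. The MHC class II list was not called without B6-Lyst replicate 1 (0.117 and 0.0884), nor against B6-albino without its replicate 3 (0.0746), nor against B6-D2 congenic without its replicates 1 (0.104) or 2 (0.0612) or the 3 arrays with high Krt12 (0.0711). Of 15 immediate early genes Atf3, Fos, Jun, Junb and Egr1 were higher than in B6-albino irides (adjusted p = 7e-06, 0.0946 with an estimated correlation) and Atf3 higher than in B6-D2 congenic irides (adjusted p = 0.00295, 0.27 with an estimated correlation). Against B6-albino, Jun was called in none of the 6 fits that left out 1 array (between 0.0671 and 0.165), Junb only without B6-albino replicate 2 (otherwise between 0.0546 and 0.14), Egr1 only without B6-albino replicate 3 (otherwise between 0.0606 and 0.114), and Fos not without B6-Lyst replicate 2 (0.0606) or B6-albino replicate 1 (0.0623). Interferon-stimulated genes had a median of 0.26 against B6-albino with 0 called (adjusted p = 0.00339, 0.885 with an estimated correlation), and turned to -0.11 (0.946) with the tissue covariates.

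Some lists lay lower in B6-Lyst than in the other two mutant strains, among them markers of lens and pigment epithelium. Lens markers had medians of -2.25 against B6-albino and -1.54 against B6-D2 congenic irides with 0 called (adjusted p = 0.000215 and 0.0151, adjusted p = 0.841 and 0.885 with an estimated correlation). B6-Lyst replicate 2 had the lowest lens mean of its strain (6.97 against 10.81 and 9.70), and without it the medians were -1.02 (0.0606) and -0.28 (0.929). The first list was also not called without B6-albino replicate 3 (0.051), the second without B6-D2 congenic replicate 2 (0.0683) or the 3 arrays with high Krt12 (0.12), and neither with the tissue covariates (0.414 and 0.428). Pigment epithelium markers had -1.05 and -0.76 with 0 called (adjusted p = 0.0151 and 0.00622, adjusted p = 0.775 and 0.705 with an estimated correlation), the first without a call when B6-albino replicate 1 (0.0521) or 3 (0.0601) or the 3 arrays with high Krt12 (0.0788) were left out, or with the tissue covariates (0.0657). Oxidative phosphorylation genes had -0.25 and -0.24 with 0 called (adjusted p = 0.00524 and 0.00741, adjusted p = 0.885 and 0.886 with an estimated correlation). Their calls ended without B6-Lyst replicate 3 (0.0839 and 0.154), the first also without B6-albino replicate 2 (0.0655), and the second without B6-D2 congenic replicate 3 (0.457) or with the tissue covariates (0.0809). Of 33 stroma genes Ogn (-0.87) and Lox (-0.77) were lower than in B6-albino irides (adjusted p = 0.0198, adjusted p = 0.841 with an estimated correlation, 0.147 without B6-albino replicate 2). With 1 array left out, Ogn was called only without B6-Lyst replicate 3 (otherwise between 0.0695 and 0.102) and Lox in no fit (between 0.053 and 0.138). Calr, a chaperone of the endoplasmic reticulum, was lower than in B6-D2 congenic irides (-0.69) among 23 genes of the unfolded protein response (adjusted p = 0.0028, adjusted p = 0.705 with an estimated correlation). Its call ended without B6-Lyst replicate 1 (0.098) or 3 (0.0737) or B6-D2 congenic replicate 3 (0.0676).

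B6-albino irides had higher Prpmp5 (3.99, SE 0.29, limma adjusted p = 0.000126), Gpnmb (3.15, SE 0.28, adjusted p = 0.00078), Otor (2.91, adjusted p = 0.0179) and the nuclear receptor Nr4a3 (1.92, adjusted p = 0.00568) than B6-D2 congenic irides, where Otor lay at 5.32, below 5.653 (at least 5.96-fold). They had lower Cck (-3.01, SE 0.33, adjusted p = 0.00352) and Lyz1 (-1.20, adjusted p = 0.0153). Otor was not called without B6-albino replicates 1 (0.135) or 2 (0.083) or B6-D2 congenic replicates 1 (0.0826), 2 (0.0934) or 3 (0.0865). Nr4a3 was not called without B6-D2 congenic replicate 2 (0.0505), and Lyz1 without B6-albino replicates 2 (0.0838) or 3 (0.0819) or B6-D2 congenic replicates 1 (0.0654), 2 (0.0934) or 3 (0.0721). There were 23 calls, 20 of them higher (87%, and 74.1% with 75th percentile scaling), with 2294 probe sets at an unadjusted p under 0.05 and arrays that did not overlap for 14.2%, where chance gives 10%. The count was 13, 14 and 14 without B6-albino replicates 1, 2 and 3 and 10 without B6-D2 congenic replicate 2. The macrophage list lay lower with 1 called member, Lyz1 (6 when adjusted over the list alone). Its median was -0.21 (adjusted p = 8.37e-05, adjusted p = 0.689 with an estimated correlation). The following lists lay lower with 0 called members. Immediate early genes had a median of -0.31 (adjusted p = 0.000463, adjusted p = 0.188 with an estimated correlation) and interferon-stimulated genes -0.31 (adjusted p = 0.000509, adjusted p = 0.841 with an estimated correlation). Schwann cell markers had -0.23 (adjusted p = 0.00339, adjusted p = 0.483 with an estimated correlation) and cell cycle genes -0.23 (adjusted p = 0.00524, adjusted p = 0.775 with an estimated correlation). The unfolded protein response had -0.11 (adjusted p = 0.0264, adjusted p = 0.841 with an estimated correlation) and complement genes -0.19 (adjusted p = 0.0274, adjusted p = 0.689 with an estimated correlation). Lens markers (0.78, adjusted p = 0.0132) and photoreceptor markers (0.53, adjusted p = 0.0151) lay higher with 0 called, and melanin genes (0.12, adjusted p = 0.0162) with Gpnmb as the 1 called member, each with adjusted p = 0.885 with an estimated correlation. The lens median was 0.20 without B6-albino replicate 3 (0.922) and not called without B6-D2 congenic replicate 1 (0.0749) or with the tissue covariates (0.907). The photoreceptor list was not called without B6-albino replicates 1 (0.163) or 3 (median 0.09, 0.966), B6-D2 congenic replicates 2 (0.0888) or 3 (0.94) or the 3 arrays with high Krt12 (0.349), or with the tissue covariates (0.967), and its median was 1.17 without B6-albino replicate 2. The melanin list was not called without B6-albino replicate 2 (0.274), B6-D2 congenic replicate 2 (0.0888) or the 3 arrays with high Krt12 (0.0979). The cell cycle list lost its call without B6-albino replicate 3 (0.0547), B6-D2 congenic replicate 2 (0.407) or those 3 arrays (0.178). The unfolded protein list lost it without B6-albino replicate 1 (0.0899), B6-D2 congenic replicates 2 (0.199) or 3 (0.0572) or those 3 arrays (0.355), or with the tissue covariates (0.117). The complement list lost it without B6-albino replicates 2 (0.0519) or 3 (0.0601) or B6-D2 congenic replicates 1 (0.0634) or 3 (0.0574), or with the tissue covariates (0.0906).

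Any difference among the 4 strains was called for 565 of 27022 probe sets, and 5951 had an unadjusted p under 0.05. The count was 260, 351 and 315 without B6-Lyst replicates 1, 2 and 3, 300 and 353 without B6-albino replicates 1 and 3, and 342 without C57BL/6J replicate 2. Called in the same direction in both of 2 mutant strains against C57BL/6J were 24 probe sets for B6-Lyst and B6-albino (7 higher and 17 lower), 4 lower ones for B6-Lyst and B6-D2 congenic, and 3 for B6-albino and B6-D2 congenic (1 higher and 2 lower). Independent lists would share 0.552 and 0.638, 0.115, and 0.00326 and 0.0167 probe sets. Simulated unchanged groups shared a median of 0, which cannot gauge what the shared C57BL/6J arrays add, since unchanged groups give few calls. The first overlap was 0 without B6-albino replicate 1 or 3 and 53 without B6-Lyst replicate 2. The other two were 0 without C57BL/6J replicate 2, B6-Lyst replicate 1 or 3, or B6-D2 congenic replicate 2 or 3. The last was also 0 without B6-albino replicate 1 or 3. Overlap of B6-Lyst and B6-D2 congenic calls was 28 without C57BL/6J replicate 1, and that of B6-albino and B6-D2 congenic calls 20 without B6-D2 congenic replicate 1. In all 3 strains 2 probe sets fell, neither of which represents a gene, and 1 is of Per2. Across probe sets, which are not independent replicates, the differences from C57BL/6J correlated with r = 0.486 for B6-Lyst and B6-albino, 0.599 for B6-Lyst and B6-D2 congenic, and 0.747 for B6-albino and B6-D2 congenic, against means of 0.462, 0.497 and 0.429 and 95th percentiles of 0.872, 0.89 and 0.919 in simulations of unchanged groups. The covariances were 0.0647, 0.0742 and 0.0941, against simulated means of 0.0266, 0.0282 and 0.028 and 95th percentiles of 0.0776, 0.0791 and 0.0982. All 6 values lay below those 95th percentiles. Part of the overlaps of calls may come from the C57BL/6J arrays, too few to split.

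Called genes were counted near the mutated loci, since strains kept by backcrossing can carry donor sequence around a selected gene. Within 20 Mb of Lyst, 4 of 351 called genes (Gpr137b, Gpr137b-ps, Tdp2 and Wdr37) were found among 95 of 13131 tested genes (odds ratio 1.61, one-sided Fisher's exact test p = 0.249), and over the whole chromosome the odds ratio was 1.72 (exact p = 0.0171). Near Tyr there were 0 of 40 called genes (exact p = 1). Near Tyrp1 and Gpnmb there was 1 of 2 (odds ratio 48.3, exact p = 0.0403), which was Gpnmb itself, and 0 of 1 when the mutated genes were left out (exact p = 1). With the mutated genes left out, 1 of 11 called genes against B6-albino (Rps6, exact p = 0.201) and 4 of 171 against B6-Lyst irides (Rps6, Zfp467, Skap2 and Hpgds, exact p = 0.454) lay near those 2 loci.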

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

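The RNA quality covariate, the tissue covariates, leaving out the 3 arrays with high Krt12, the weights estimated gene by gene and the position test without mutated genes were chosen after the result was seen. Counts of called probe sets are given for B6-Lyst, B6-albino and B6-D2 congenic against C57BL/6J unless named otherwise, beside 684, 94 and 11 as reported (498 for B6-Lyst and B6-albino, 252 for B6-Lyst and B6-D2 congenic, 23 for B6-albino and B6-D2 congenic, 565 for any difference). Overlaps of calls are given for B6-Lyst with B6-albino, B6-Lyst with B6-D2 congenic and B6-albino with B6-D2 congenic, beside 24, 4 and 3. Counts left out moved by at most 1.5 times. Except where fewer probe sets, fewer arrays or a stricter threshold gave lower counts, the cause was not tested.

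Scaling and filter moved the smaller counts. Quantile normalization gave 219 calls for B6-albino and 36 for B6-D2 congenic, with overlaps of 61, 17 and 16, and 75th percentile scaling gave 177 and 39, with overlaps of 45, 23 and 11. Without a filter B6-D2 congenic had 18 calls. With a filter at the 60th percentile there were 25 and 5 for B6-albino and B6-D2 congenic, 318 for B6-Lyst and B6-albino, 137 for B6-Lyst and B6-D2 congenic, 347 for any difference, and overlaps of 7, 1 and 0. With trend=FALSE B6-albino had 160. With strain means below the filter value set to it, the median of the lens list in B6-D2 congenic irides went from 2.20 to 1.97, and no other list median against C57BL/6J moved by over 0.063.

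Array weights gave 8344, 15124 and 4333 calls, 7156, 380 and 522 for the mutant pairs and 16966 for any difference, overlaps of 4809, 2842 and 3435, and 3 and 5 called lists for B6-albino and B6-D2 congenic, in place of 9 each. That fit did not converge and gave C57BL/6J replicate 2 a weight of 23.1. Gene by gene array weights gave 5399, 9601 and 3200 calls, 5901, 449 and 638 for the mutant pairs and 11665 for any difference, overlaps of 2440, 1760 and 2112, and 4 called lists for B6-albino, with a weight of 6.23 for that array. Of 29 list calls, 12 and 10 ended and 3 and 3 turned direction under the 2 kinds of weights. The mean of the interferon list turned to 0.184 and 0.133 in B6-Lyst and to 0.208 and 0.157 in B6-D2 congenic irides, and that of the photoreceptor list to -0.429 and -0.251 in B6-Lyst irides.

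With only the 6 arrays of the strains compared there were 280, 15 and 3 calls, and 8 for B6-albino and B6-D2 congenic. Representative probe sets alone gave 387, 34 and 1, 12 for B6-albino and B6-D2 congenic and 333 for any difference. A change of at least 2-fold left 231 and 49 for B6-Lyst and B6-albino, 227 for B6-Lyst and B6-albino compared with each other, and 268 for any difference. An adjusted p under 0.01 left 242, 0 and 4, 222 for B6-Lyst and B6-albino, 11 for B6-albino and B6-D2 congenic and 220 for any difference. Beside the 0, B6-albino had 5246 probe sets at an unadjusted p under 0.05 in limma. With an estimated correlation 0 lists were called in each of the 3 comparisons, and the rank version changed no count of lists by over 1.5 times.

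With the replicate number as a block, the count was 0 for B6-albino and 5 for B6-D2 congenic, and the overlaps were 0, 1 and 0. The numbers do not pair the arrays. The 18 pairs with the same number had correlations of their deviations from the strain means between -0.434 and 0.389, and 2 of 12 arrays correlated best with their own number. The block changed no other count by over 1.5 times, and all 29 list results kept their call with it.

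The RNA quality covariate gave 27 and 7 calls for B6-albino and B6-D2 congenic, 1119 for B6-Lyst and B6-albino, 57 for B6-albino and B6-D2 congenic, and overlaps of 11, 2 and 1. The tissue covariates gave 0 and 4 for B6-albino and B6-D2 congenic, 214 for B6-Lyst and B6-albino, 13 for B6-albino and B6-D2 congenic, 259 for any difference, overlaps of 0, 0 and 0, and 2 called lists for B6-albino. They take out the lens and retina markers by construction, so that the mean of the lens list was 0 in B6-albino and 0 in B6-D2 congenic irides and that of the photoreceptor list 0.003 in B6-albino irides, while the interferon list turned to 0.171 in B6-D2 congenic irides. Without the 3 arrays with high Krt12 there were 0 and 6 calls for B6-albino and B6-D2 congenic, 237 for B6-Lyst and B6-albino, 6 for B6-albino and B6-D2 congenic, 256 for any difference, overlaps of 0 for B6-Lyst with B6-albino and 0 for B6-albino with B6-D2 congenic, and 5 called lists for B6-albino, and the vascular endothelium list turned to 0.107 in B6-albino irides.

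With each of the 6 arrays of the strains compared left out in turn, the counts lay between 252 and 902, 0 and 87, and 4 and 44, and those of the mutant pairs between 232 and 341, 181 and 235, and 10 and 16. Arrays of the other strains enter through the shared spread. Over all 12 arrays the highest counts were 200 for B6-albino (without B6-Lyst replicate 2), 665 for B6-Lyst and B6-albino (without B6-D2 congenic replicate 3), 262 for B6-Lyst and B6-D2 congenic (without C57BL/6J replicate 1) and 25 for B6-albino and B6-D2 congenic (without C57BL/6J replicate 1 or B6-Lyst replicate 3). The count of any difference lay between 260 and 636. Overlaps lay between 0 and 53, 0 and 28, and 0 and 20, and called lists between 8 and 13, 6 and 10, and 8 and 13. The mean of the interferon list lay between -0.56 and 0.057 in B6-Lyst and between -0.527 and 0.09 in B6-D2 congenic irides. Of 176 results of named genes, calls lost numbered 28 with only the 6 arrays, 25 with the block, 12 with the RNA quality covariate, 23 with the tissue covariates and 30 without the arrays with high Krt12, and no called one turned direction. In B6-Lyst irides the calls of Ciart (0.0574), Egr1 (0.052), Cd4 (0.0786) and Srxn1 (0.0706) ended with only the 6 arrays. Of 1056 results of named genes in the fits with 1 array left out 905 were the same, 121 lost a call, 6 gained one, 24 without a call changed sign and no called one did, and of 348 list results 324 kept their call and 24 lost it, 2 of them with a changed sign. Of the lists called between mutant strains, 6 of 11 (B6-Lyst and B6-albino), 7 of 10 (B6-Lyst and B6-D2 congenic) and 4 of 10 (B6-albino and B6-D2 congenic) were called in all 6 such fits. Several values of members that were not called rested on 1 array. Without C57BL/6J replicate 3, Rsad2 was -0.72 in B6-albino and -0.30 in B6-D2 congenic irides, Gbp2 -0.57 in B6-albino and Ifit2 -0.40 in B6-Lyst irides, and Gnat1 was 1.17 in B6-albino and 0.70 in B6-Lyst irides. Ifit3 was -0.47 in B6-Lyst irides without B6-Lyst replicate 3, and Stab1 lay between -0.32 and 0.04.

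The odds ratio of called genes near a mutated locus over the whole chromosome was 1.72 for B6-Lyst and 7.78 for B6-D2 congenic. It was 0 for the B6-D2 congenic strain with the mutated genes left out. The offset of log2(value + 1) was not run, since the deposited values were already on a log scale. The filter left out probe sets that were low on average over all arrays, not those low in 1 strain. Of the called probe sets, 72 of 684, 20 of 94 and 3 of 11 had 1 of the 2 strain means below the filter value, where a level is not shown to lie above background. The 3 arrays per strain limit what can be called.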

Other observations

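Chosen after the result was seen were the strain against all others counts and most tests of causes. For the clock and lens patterns these were time of day, labelling batch, RNA quality of C57BL/6J replicate 3 and strain. For the macrophage markers they were labelling batch, hybridization, RNA quality and more macrophages. The tests of lens carry-over and of other splits of the arrays were chosen before.

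Transcripts that set B6-Lyst irides apart from each of the other 3 strains, with a call in all 3 comparisons, numbered 194 higher probe sets of 151 genes and 1 lower one, of Prpmp5. Beside the genes named above they included Cd36, a scavenger receptor that takes up lipids, whose mean lay 3.68 above 5.653 on the log2 scale, with those of the other 3 strains below that value. By their smallest difference from another strain they also included the pattern receptor Clec7a (3.74), Cybb, a subunit of the phagocyte oxidase (3.27), Mpeg1, which encodes a pore-forming protein of macrophages (3.05), Ptprc, the common leukocyte antigen (2.56), and the kinase Syk (1.84). B6-albino irides stood apart by 6 higher probe sets of 5 genes (Prpmp5, Wdfy1, Cyp4b1, Car6 and Brca1) and by 1 lower one, of Lyz1. B6-D2 congenic irides stood apart by 5 lower probe sets, 1 of Gpnmb and 4 unnamed here. With 1 array left out, the higher counts lay between 146 and 199 for B6-Lyst and between 0 and 5 for B6-albino irides, and the lower count of B6-D2 congenic irides between 4 and 7. The B6-albino counts were 0 higher and 0 lower without B6-albino replicate 1 or 3, with the tissue covariates or without the 3 arrays with high Krt12. These genes were named after their values were seen.

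Prpmp5 and Cck differed between strains in ways that followed no single comparison. Prpmp5 averaged 10.16 in C57BL/6J, 7.05 in B6-Lyst, 12.46 in B6-albino and 8.47 in B6-D2 congenic irides, and the last differed from C57BL/6J by -1.69 (limma adjusted p = 0.0663). Cck averaged 8.35, 6.81, 6.69 and 9.70 in the same order. It was called between B6-D2 congenic and each of the other mutant strains, and differed by 1.35 from C57BL/6J (adjusted p = 0.122).

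Macrophage markers were higher in B6-Lyst irides, and technical causes were weighed against a larger or altered macrophage population. Labelling batch, as read from the spike level, is argued against as the whole cause, since the median of the 21 markers was 1.551 above B6-D2 congenic irides, which also lie at the low spike level (1.586 without B6-Lyst replicate 3, whose spikes were the highest among the mutant arrays), and the lowest B6-Lyst array mean lay 1.259 above the highest of any other strain. The B6-Lyst and B6-D2 congenic samples stand in different blocks of records, so this median does not test a batch that followed those blocks. The C57BL/6J samples stand in the same block as B6-Lyst but differ in spike level. The hybridization spikes set the B6-Lyst arrays (mean 10.09) apart from those of every other strain. Genes of like mean expression did not share the rise, since 1000 random lists matched on it had medians of at most 0.238. Arrays with like column medians hold such list medians near 0 in any case. These lists therefore cannot argue against a hybridization difference, which stays open. RNA quality is argued against, since the median was 1.739 with the RNA quality covariate. More macrophages of an unaltered profile would raise all markers, and by a like factor those that only macrophages make. Cd163 was at -1.095 (-0.503 without B6-Lyst replicate 2), but at 5.01 in B6-Lyst irides, below 5.653, its fall is at least 0.456. Whether it or Pf4 (-0.51, and -0.065 without that array) was lowest is not settled, and 0 markers were called lower. The rises were uneven, with Lyz2 at 3.864 and Tyrobp at 3.001 beside Mrc1 at 0.632 and Fcgr2b at 0.195, both not called. Which of these markers only macrophages make was not measured, so the uneven rises cannot decide whether the profile was altered. A larger population as the whole or part of the cause stays open, as does an altered profile. The call count of this comparison was 684 for the real strains and at most 30 for the other splits of the 6 arrays, which are too few for a share under 0.05.

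The clock list was called lower in each mutant strain than in C57BL/6J irides at the preset correlation and in none with an estimated one, with 5 called members in B6-Lyst, 1 in B6-albino and 0 in B6-D2 congenic irides. An index of 9 clock genes minus 2 others was 2.365 in C57BL/6J and 1.384 in the mutant arrays, but these genes were examined because they had been seen to differ, so the index can exclude a cause but supports none. A different time of day at collection stays open and is not supported by it. It would need Arntl and Clock to lie above C57BL/6J in the mutant strains, and the smallest such difference was 0.203. RNA quality of C57BL/6J replicate 3 is argued against, since the other C57BL/6J arrays lay at least 0.293 above all mutant arrays. Labelling batch cannot be told apart from strain, since the spike difference of 3.22 followed the same split, and times of collection are not given in the sources used here. An effect of the mutations on the clock genes was not tested.

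Lens markers differed between arrays of the same strain. Uneven carry-over of lens tissue at dissection is a candidate explanation. The median correlation of the 20 markers' deviations from their strain means was 0.843, where 1000 random lists gave a median of 0.0598 and a 95th percentile of 0.242. A strain difference in lens transcripts stays open, since C57BL/6J against the mutant strains had an exact permutation p of 0.118.

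For the other counts, the real strains and the highest other split gave 94 and 0 (B6-albino and C57BL/6J), 11 and 1 (B6-D2 congenic and C57BL/6J), 498 and 0 (B6-Lyst and B6-albino), 252 and 0 (B6-Lyst and B6-D2 congenic), and 23 and 0 (B6-albino and B6-D2 congenic). In each, 1 of 10 splits gave as many calls, the real one, and the splits are too few for a share under 0.05. For any difference among the 4 strains, 1 of 100 splits, the real one, gave 565 calls and the highest other 217. This is the smallest share that 100 splits can give, so chance is argued against there but not excluded. The count was 260 without B6-Lyst replicate 1, and the splits do not tell strain from spike level.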
